A study of Rattus norvegicus with 4 samples.

How the data were processed

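Total RNA of rat INS-1 cells, an insulin-secreting line derived from a rat insulinoma, was measured on 4 Affymetrix arrays, per the labels' protocols. A group of cells was kept in 11.2 mM glucose and another in 22.4 mM, each for 7 days. RNA was extracted with a silica-column kit, amplified, and hybridized as biotin-labelled, fragmented single-stranded cDNA, per the labels' protocols. The titles place 2 arrays in each glucose group and number them as replicates 1 and 2. They do not say whether the replicates were separate cultures. Every p-value of a single gene therefore measures the spread between these arrays, which may be technical.

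The authors deposited 1 table of 36685 probe sets with a log2 value for each array. Base 2 was inferred from the range of the deposited values, which ran from 2.23 to 13.2, and is not stated in the sources used here. The background correction, normalization, summarization and software behind these values are not given in the sources used here. Array medians were 4.76 and 4.79 at 11.2 mM and 4.80 and 4.73 at 22.4 mM, so the arrays were nearly level in median as deposited. Background levels are not given in the sources used here, so no probe set was shown to be above background, and a difference from a dim signal can be understated. The values were used as deposited, with no further normalization and no filter on dim signals. The number of arrays limits the precision: the median standard error of a log2 difference was 0.12.

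Gene names came from the platform annotation supplied with the table, which can be old. It lists 15653 of the probe sets, 14824 of them with 1 gene symbol and 829 with several, and the other 21032 are unnamed here. The Entrez identifiers of 14670 probe sets were found in a RefSeq gene table of assembly GRCr8, used for names alone, and 0 symbols changed. A probe set with several symbols was left unnamed. The 14824 probe sets stand for 14557 genes. For the 234 genes with several probe sets the brightest over all 4 arrays was used, and in 91 of these genes the probe sets differed in the sign of the difference. Control probe sets could not be told from others in the tables used, so all 36685 probe sets were tested where a test without controls had been planned. No coordinates are given, because the genome build behind the array annotation is not given in the sources used here.

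Glucose groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, 2 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all probe sets with a threshold of 0.05. Every difference is 22.4 mM minus 11.2 mM on the log2 scale, so that a difference of 1 is a 2-fold change. Confidence intervals are 95% intervals of the moderated fit. A set of 28 gene lists was fixed with the tests before the data were examined. It was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. That test sets the genes of a list against all other genes. At the preset correlation its p-values rest on the spread over genes and do not measure the spread between arrays. Camera with an estimated correlation, and fry, were run beside it. Of the 582 list entries, 414 were named on the array, and Pdx1 was not among them. Replicate agreement was described by mean absolute log2 differences between arrays, without a test.

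Genes named in the text followed a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls past the threshold without overlap of the groups. Where fewer passed, it filled each direction to 6 genes by the smallest unadjusted p among probe sets at or above the median signal of 4.76, leaving out numbered loci, chemosensory receptors and small RNAs. It also took up to 4 members past the threshold of each list past camera and up to 2 of any other list, and always Ins1, Ins2, Pdx1, Mafa, Slc2a2 and Txnip, with a further gene that is not reported here. As no probe set passed over all probe sets, "past the threshold" was read for list members as adjusted over the list alone. Where no member passed even so, the 4 largest differences of a list past camera were taken. Both readings were settled after the values had been seen.

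The code was tested on simulated data. In 36685 simulated probe sets with the spread of these arrays, the fit called 82 of 100 probe sets changed by 2 on the log2 scale and 6 of 100 changed by 1, with 6 false calls. The simulated spread was independent between probe sets, and no simulated array lay apart from the others. These shares are therefore not the power of the real comparison. In 14557 simulated independent genes, camera called 20 of 20 lists of 15 genes shifted by 0.3 and 0 of 100 unshifted lists. That simulation held no correlation between genes, so it does not bear on the difference between preset and estimated correlations. Settings varied as laid down beforehand were the normalization, the probe sets tested, the variance prior, the test, the arrays used and a block for the replicate numbers. Others were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.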

Results

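The series asks how gene expression in an insulin-secreting cell line differs after a week in high glucose, a culture model of glucotoxicity. INS-1 cells, which come from a rat insulinoma and are used as a model of pancreatic beta cells, were kept for 7 days in 11.2 mM glucose (n = 2) or 22.4 mM glucose (n = 2). Each of the 4 arrays gave a log2 signal for 36685 probe sets, of which 14824 carried 1 gene symbol. Array medians lay between 4.73 and 4.80.

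On average, arrays of different glucose differed slightly more than replicate arrays. Pairs of replicate 2 of 11.2 mM with the 22.4 mM arrays differed less than the 11.2 mM replicates did. The mean absolute log2 difference between replicates was 0.213 at 11.2 mM and 0.172 at 22.4 mM. Between the groups it was 0.246 and 0.242 for pairs with replicate 1 of 11.2 mM, and 0.188 and 0.195 for pairs with replicate 2. The mean of the between-group values was 1.13 times that of the within-group values. Replicate 1 of 11.2 mM thus lay farther from each of the other 3 arrays than these lay from each other, and no arrays were identical.

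The rat insulin genes stood apart from each other. Ins2 (probe set 17638641), 1 of the pair of rat insulin genes, had a log2 signal of 10.62 ± 0.084 (SD, n = 2) at 11.2 mM and 8.78 ± 0.075 (SD, n = 2) at 22.4 mM, which was 3.57-fold lower. Ins1 (17626410), the other insulin gene, had 10.90 ± 0.12 (SD, n = 2) and 11.08 ± 0.080 (SD, n = 2), a log2 difference of 0.18 with a 95% interval from -0.12 to 0.48. The coding sequences of these genes are closely alike and the probe sequences were not used here, so signal shared between them is not excluded. Slc2a2 (17737579), the beta cell glucose transporter, differed by -0.13 (SE 0.096). Mafa (17838270), a transcription factor that drives insulin genes, differed by -0.57 (SE 0.16), and by -0.37 without replicate 1 of 11.2 mM. Both arrays of 22.4 mM lay below both of 11.2 mM in Mafa, Ins2 and Slc2a2, and above them in Ins1 and Txnip. Such a lack of overlap was met in 40.6% of all probe sets. Without replicate 2 of 11.2 mM the Ins1 difference was 0.094. Txnip (17741001), a glucose-induced inhibitor of thioredoxin, was 1.95-fold higher, with a log2 difference of 0.96 (SE 0.10). No value of Pdx1 is reported, since no probe set used here named it.

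The genes with the smallest unadjusted p among brighter probe sets were, on the higher side, Prok2, Rasgrp2, S100a4, Cnksr2, C1galt1 and Adora2b. Prok2 (17793620), which encodes the secreted peptide prokineticin 2, was 6.38-fold higher at 22.4 mM, with a log2 difference of 2.67 (SE 0.19). Rasgrp2 (17623498), an exchange factor for the small GTPase Rap, had a log2 signal of 5.08 at 11.2 mM and 7.16 at 22.4 mM, and S100a4 (17740414), a calcium-binding protein, had 4.74 and 6.78. Their signals at 11.2 mM were dim and not shown to be above background, so no exact size is given for these differences. The log2 differences were 1.61 for the scaffold protein Cnksr2 (17872391) and 1.56 for the glycosyltransferase C1galt1 (17781523), and the adenosine receptor Adora2b (17646654) was 2.83-fold higher. On the lower side stood Ins2, the vitamin D receptor gene Vdr (17840592) with 6.82 at 11.2 mM and a likewise dim 5.17 at 22.4 mM, and the insulin receptor-related receptor Insrr (17739640) with -1.44 (SE 0.10). Pcp4l1 (17686577) differed by -1.36, the monoamine oxidase Maob (17870839) by -1.14 and the aromatic amino acid transporter Slc16a10 (17759134) by -1.10. In each of these 12 genes both arrays of a group lay apart from both arrays of the other, as a choice by the smallest p makes likely.

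**Figure D1:**
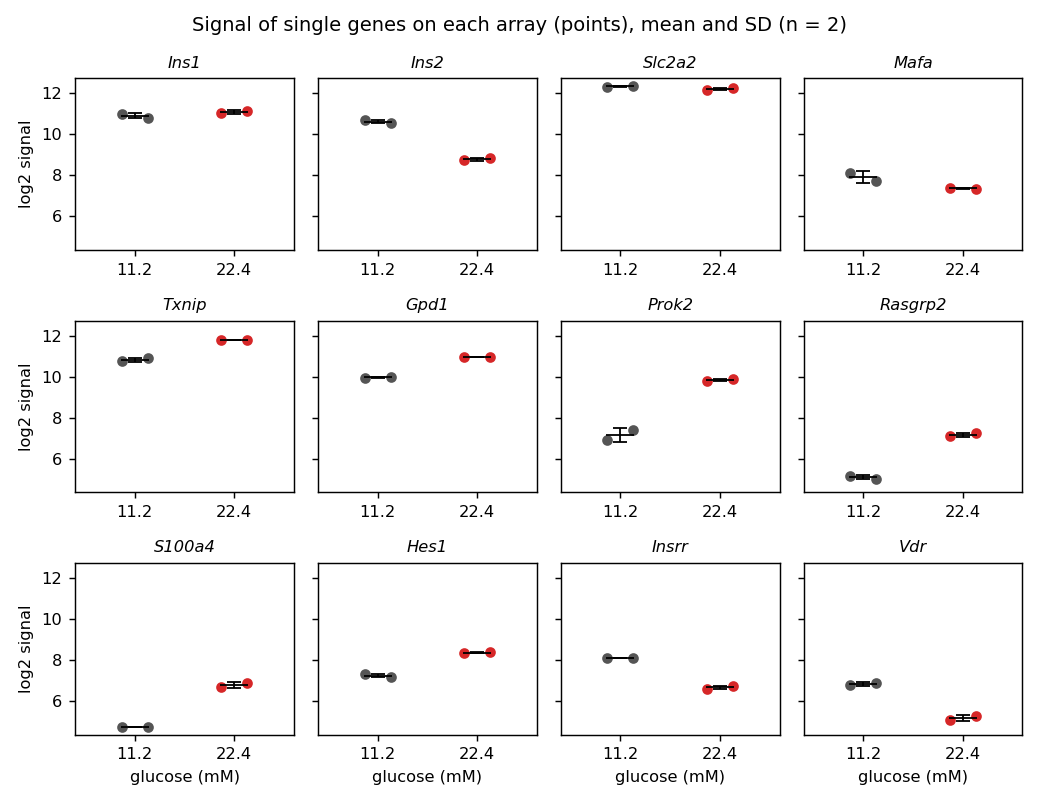
Log2 signal (y axis) of 12 genes on each array, by glucose concentration in mM (x axis), with points for arrays and black marks for the mean and SD of 2 arrays. Ins2 lay near 10.62 at 11.2 mM and 8.78 at 22.4 mM, while Ins1 lay near 10.90 and 11.08.

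None of these single-gene differences passed the test over all probe sets. Limma with Benjamini-Hochberg adjustment called 0 of 36685 probe sets, and the lowest adjusted p was 0.218. At an unadjusted p under 0.05 there were 3344 probe sets, 1601 higher and 1743 lower, where 1834 would be met by chance. Without replicate 2 of 11.2 mM this number was 5709, and without replicate 1 or 2 of 22.4 mM it was 2139 or 2114. In 178 probe sets the groups differed at least 2-fold without overlap, 118 higher and 60 lower. Over all probe sets 40.6% showed no overlap, against 33.3% by chance. A planned fit of the 14824 probe sets with 1 gene symbol called 62, 43 higher and 19 lower. The 12 genes above and Txnip were among the 62, Ins2 with an adjusted p of 0.0102 and Txnip with 0.0322. These calls come from the same arrays and are not separate evidence. Over the alternatives tried, adjusted p ranged from 0.0102 to 0.827 for the 12 genes, and for Txnip from 0.0322 to 0.827.

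Among the 28 gene lists, camera with the preset correlation placed 10 past the threshold, 7 higher and 3 lower at 22.4 mM. Its p-values treat genes, not arrays, as the replicates, so small ones do not show that a shift would recur in new cultures. None of the 10 passed with an estimated correlation, where each had an adjusted p of 0.678, and the lowest unadjusted p of any list was 0.0324. That setting of camera rests on the 2 residual degrees of freedom, so a list can hardly pass it whatever its correlation. For glucose sensing and channels the estimated correlation was -0.013, under the preset 0.01, yet the camera p rose from 3.40e-07 to 0.0324. For cell cycle genes the estimate was 0.98, for ATF4 stress genes 0.82, for cholesterol synthesis 0.81 and for insulin granule genes 0.63. It was 0.41 for fatty acid synthesis, 0.24 for carbohydrate response targets, 0.16 for the TCA cycle, 0.14 for antioxidant genes and 0.12 for glycolysis. These lie above the preset, so the preset p-values of these lists can be too small. A call lost with the estimated correlation is still not by itself a sign of correlated members. Fry called 0 lists for movement in a common direction and 8 for change in either direction, of which 3 were among the 10 and 5 were not. The 5 were beta cell transcription factors and dedifferentiation (fry adjusted p = 0.0064 each), exocytosis (0.0137), and the interferon response and apoptosis (0.0236 each). No member of any list passed over all probe sets, so the counts below of members past the threshold are adjusted over the list alone.

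Carbohydrate response targets, genes induced through the glucose-responsive factor ChREBP and its partners, were shifted higher, with a median log2 difference of 0.43 over 13 genes (camera adjusted p = 8.16e-05, and adjusted p = 0.678 with an estimated correlation). Adjusted over the list alone, 9 members passed, 8 higher and 1 lower. The largest were Bhlhe40 (17785849), a transcriptional repressor, with 1.14 (SE 0.20), the pyruvate kinase Pklr (17739986) with 1.03 (SE 0.29), the glycerol-3-phosphate dehydrogenase Gpd1 (17832266) with 1.00 (SE 0.093) and Txnip with 0.96. The difference of Pklr was 0.61 without replicate 1 of 11.2 mM. Glycolysis and lactate genes had a median of 0.21 over 11 genes (adjusted p = 0.00890, and adjusted p = 0.678 with an estimated correlation), with 10 positive. Of these, Pfkfb3 (17716849), which makes the activator of phosphofructokinase, was higher by 1.10 (SE 0.17) and the phosphofructokinase Pfkl (17754172) by 0.73 (SE 0.17), while the neuronal enolase Eno2 (17794801) differed by -0.72 (SE 0.16). These 3 passed when adjusted over the list alone. Without replicate 1 of 11.2 mM the glycolysis median was 0.091, and without replicate 2 of 22.4 mM it was 0.12. The TCA cycle list had a median of 0.13 over 18 genes (adjusted p = 0.00139, and adjusted p = 0.678 with an estimated correlation). Its median was 0.069 without replicate 1 and 0.20 without replicate 2 of 11.2 mM. Pdhb (17697648), a subunit of pyruvate dehydrogenase, was its 1 member past the threshold, with 0.91 (SE 0.12).

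Lipid synthesis genes were shifted higher. All 15 measured genes of cholesterol synthesis had positive differences, from 0.21 for Ebp to 1.61 for Hsd17b7, and the groups did not overlap in 13 (median 0.67, adjusted p = 5.35e-08, and adjusted p = 0.678 with an estimated correlation). Ebp and Hsd17b7 were chosen after their values were seen, as the ends of this range. The phosphomevalonate kinase Pmvk (17740143) was the 1 member that passed adjusted over the list alone, with 0.83 (SE 0.15). The list's median was 0.32 without replicate 1 of 11.2 mM and 1.01 without replicate 2. Fatty acid synthesis genes had a median of 0.23 over 15 genes (adjusted p = 0.00854, and adjusted p = 0.678 with an estimated correlation), and 0 members passed over the list alone. The largest differences were 1.31 (SE 0.29) for the acetyl-CoA synthetase Acss2 (17767961), 1.11 (SE 0.40) for the elongase Elovl6 (17742626), 0.59 (SE 0.15) for the phosphatidate phosphatase Lpin1 (17821143) and -0.55 (SE 0.45) for the acyltransferase Dgat2 (17635148). Without replicate 1 of 11.2 mM the fatty acid list lost its call (median 0.10, adjusted p = 0.0673), Elovl6 differed by 0.53 and Dgat2 turned to 0.14. Without replicate 2 of 11.2 mM the list's median was 0.44, and Elovl6 and Dgat2 differed by 1.70 and -1.23. Over all alternatives the adjusted p of this list ranged from 4.39e-04 to 0.678.

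All 21 measured cell cycle genes had positive differences, and the groups did not overlap in 16 (median 0.46, adjusted p = 3.22e-08, and adjusted p = 0.678 with an estimated correlation). Adjusted over the list alone, 0 members passed. The mitotic kinases Aurkb (17647342) and Aurka (17779738) differed by 0.76 (SE 0.23) and 0.67 (SE 0.27), the anaphase activator Cdc20 (17809960) by 0.68 (SE 0.34) and the spindle checkpoint kinase Bub1b (17764890) by 0.65 (SE 0.26). Replicate 1 of 11.2 mM lay below replicate 2 by a median of -0.56 over these genes. Without replicate 1 the median difference was 0.19, and those of Aurkb, Aurka, Cdc20 and Bub1b were 0.45, 0.28, 0.18 and 0.28. Without replicate 2 the median was 0.77, and Aurka, Cdc20 and Bub1b differed by 1.06, 1.17 and 1.03. Antioxidant genes had a median of 0.21 over 17 genes (adjusted p = 3.21e-04, and adjusted p = 0.678 with an estimated correlation). The glutathione synthetase Gss (17778591) was the 1 of them that passed adjusted over the list alone, with 0.86 (SE 0.12).

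Genes of glucose sensing and ion channels were shifted lower, with 12 of 14 negative, no overlap in 11 and a median of -0.29 (adjusted p = 3.17e-06, and adjusted p = 0.678 with an estimated correlation). Adjusted over the list alone, 6 passed, all lower. The calcium pump Atp2a3 (17648173) differed by -0.70 (SE 0.12), the incretin receptor Gipr (17630198) by -0.66 (SE 0.10), the ATP-sensitive potassium channel subunit Kcnj11 (17633066) by -0.62 (SE 0.10) and the adenylate cyclase Adcy8 (17837674) by -0.46 (SE 0.099). Signals of Adcy8, 5.51 at 11.2 mM and 5.05 at 22.4 mM, were dim, so the size of its difference is not exact. Insulin granule and hormone processing genes had a median of -0.16 over 16 genes, 13 of them negative (adjusted p = 0.00172, and adjusted p = 0.678 with an estimated correlation). Of these, Ins2 and the neuropeptide Npy (17783542), with -1.10 (SE 0.16), passed when adjusted over the list alone. The median of this list was -0.095 without replicate 1 of 11.2 mM.

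The ATF4 stress list, genes of amino acid synthesis and stress induced by the transcription factor ATF4, had a median of -0.59 over 22 genes, 21 of them negative (adjusted p = 3.21e-04, and adjusted p = 0.678 with an estimated correlation). The groups overlapped in 15 of the 22, and 0 passed adjusted over the list alone. This shift rested on replicate 1 of 11.2 mM, which exceeded replicate 2 by a median of 1.27. Trib3 (17778298), a pseudokinase, had 8.75 on that array against 5.06, 5.08 and 5.12 on the others, for a difference of -1.80 (SE 1.21). The differences were -1.46 (SE 0.86) for the glutathione-degrading enzyme Chac1 (17765084), -1.21 (SE 1.22) for the cystine transporter Slc7a11 (17747235) and -0.93 (SE 0.40) for the serine enzyme Shmt2 (17836571). Without replicate 1 of 11.2 mM the list's median was 0.045 and its call was lost (adjusted p = 0.302); Trib3 then differed by 0.046, Chac1 by -0.14, Slc7a11 by 0.66 and Shmt2 by -0.34. Signals of Slc7a11 on the remaining arrays, 3.24, 3.73 and 4.06, lay under the median of all probe sets and were not shown to be above background, so neither the size nor the sign of its differences is settled. Trib3 was likewise dim on those arrays, so the sizes of its differences are not exact and its sign without replicate 1 is not settled. Without replicate 2 the list's median was -1.22, and Trib3, Chac1, Slc7a11 and Shmt2 differed by -3.65, -2.78, -3.07 and -1.52. Over all alternatives the list's adjusted p ranged from 1.91e-18 to 0.678.

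**Figure D2:**
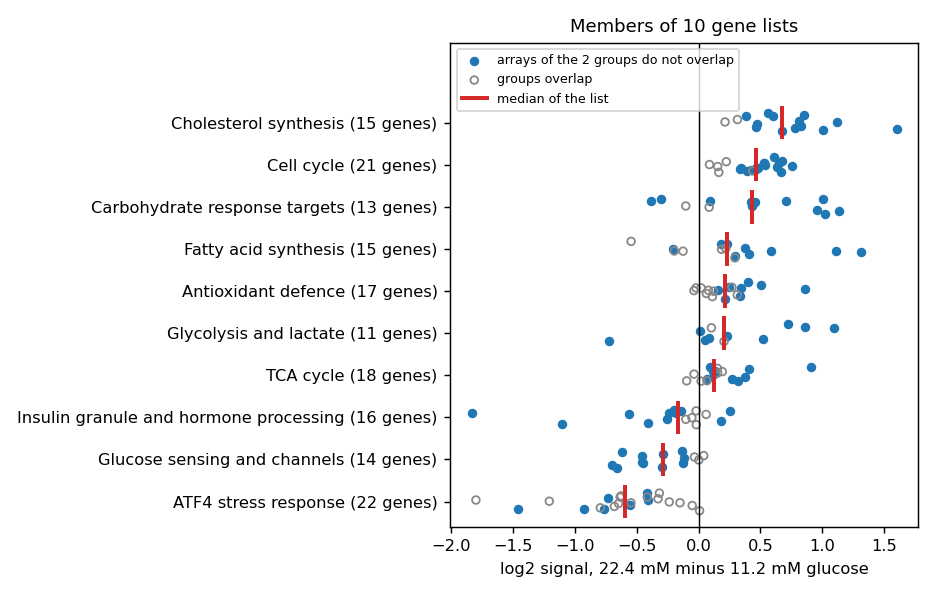
Log2 differences (x axis, 22.4 mM minus 11.2 mM) of the members of the 10 lists past the threshold (y axis, with the number of genes), filled where the arrays of the groups did not overlap and open where they did, with a red line at each median. The medians ran from -0.59 for the ATF4 stress list to 0.67 for cholesterol synthesis.

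**Figure D3:**
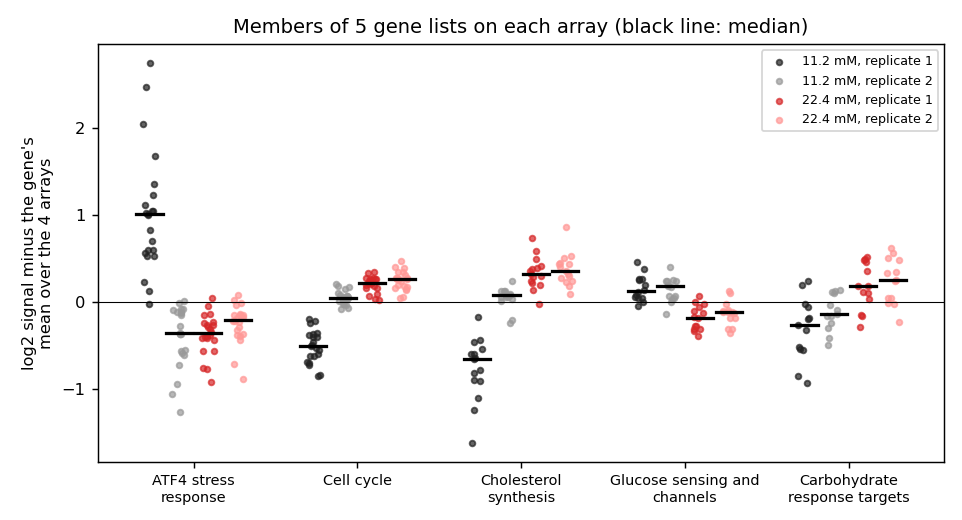
Log2 signal of each member of 5 lists on each array, minus that gene's mean over the 4 arrays (y axis), by list (x axis), with colours for arrays and black lines for medians. Replicate 1 of 11.2 mM had a median of 1.01 in the ATF4 stress list, -0.51 in the cell cycle list and -0.66 in the cholesterol synthesis list.

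The other 18 lists did not pass camera. Beta cell transcription factors had a median log2 difference of -0.061 (adjusted p = 0.0799). Without replicate 1 of 11.2 mM or replicate 2 of 22.4 mM this list passed, lower, with adjusted p = 0.0116 and 0.0353. Without replicate 2 of 11.2 mM its median was -0.022 (adjusted p = 0.513), and without replicate 1 of 22.4 mM it was 0.014 (adjusted p = 0.306). Over all settings its highest adjusted p was 0.678. Apoptosis and growth arrest genes had 0.17 (adjusted p = 0.0864), and without replicate 1 of 22.4 mM passed, higher, with adjusted p = 0.0245. In the other fits without 1 array its adjusted p was 0.0673, 0.145 and 0.247, and over all settings its highest was 0.678. In this list Ccng1 (17655535), a p53 target, with 0.70 (SE 0.15), and the anti-apoptotic gene Bcl2 (17683445), with -0.50 (SE 0.10), passed adjusted over the list alone. Of the hypoxia list (median 0.025, adjusted p = 0.293), the prolyl hydroxylase Egln3 (17821879) and the pyruvate dehydrogenase kinase Pdk1 (17762924) passed adjusted over the list alone, with 1.43 (SE 0.15) and 0.68 (SE 0.13). Of the exocytosis list (-0.021, adjusted p = 0.408), Syt13 (17764207) and Rab27a (17845817), proteins of granule traffic, passed with -0.65 each (SE 0.11 and 0.096). Of the dedifferentiation and progenitor list (-0.011, adjusted p = 0.959), the Notch target Hes1 (17669934) passed with 1.12 (SE 0.10). In the remaining lists 0 members passed adjusted over the list alone.

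Medians of these were -0.091 for insulin and IGF signalling (adjusted p = 0.155), -0.13 for chaperones and the unfolded protein response (0.155), 0.091 for the interferon response (0.408) and 0.0012 for oxidative phosphorylation (0.444). Cytosolic ribosomal proteins had 0.058 (adjusted p = 0.525), immediate early genes -0.082 (0.740), fatty acid oxidation -7.5e-05 (0.925), genes disallowed in beta cells -0.064 (0.959) and inflammation 0.029 (0.991). Lists of markers of other cell types did not pass either. Their medians were 0.018 for acinar and ductal cells (adjusted p = 0.747), 0.032 for stromal and endothelial cells (0.888), 0.028 for other islet hormones (0.959) and -0.0032 for immune cells (0.959). The sign of the median, the mean or the test differed in the stromal and endothelial, immune, inflammation, disallowed and dedifferentiation lists.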

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

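The fits that combine a choice of probe sets with a variance prior, the threshold of 0.1 and the fits that separate the adjustment from the prior were chosen after seeing the data. Limma called 0 probe sets over all 36685 under each change of normalization, centring, test, prior and array left out, and 0 among those at or above the median signal. Among probe sets with 1 gene symbol it called 62, or 60, 73 and 77 with a robust prior, a trend and both. Adjusting the p-values of the fit on all probe sets over the named ones alone gave 0, and adjusting the fit of the named ones as over all probe sets gave 8, so fewer tests alone did not give the 62 calls, and the prior estimated from named probe sets (3.96 prior degrees of freedom, against 2.71) gave part of them. At an adjusted p under 0.1, all probe sets gave 0 under the 4 priors, named ones gave 211, 207, 207 and 210, and those at or above the median signal gave 0 and 0 without a trend, 108 with a trend and 48 with trend and robust prior; the cause was not tested. A rule of size without a p, 2-fold without overlap, took 178.

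Leaving out 1 array at a time, where the lone array of a group was assumed to vary like the other group, the number at unadjusted p under 0.05 ranged from 2114 to 5709 and the number 2-fold apart from 191 to 574. With named probe sets alone these were 1912 and 91, from fewer probe sets. With 1 array in a group, lack of overlap is met more often by chance. The range of 2-fold numbers without 1 array is therefore not on the footing of the 178 from all 4 arrays. Of the 10 gene lists past camera, 0 remained with an estimated correlation and 0 with directional fry. The loss with an estimated correlation can come from its 2 residual degrees of freedom, from correlated members or from both. For glucose sensing and channels the estimated correlation of -0.013 lay under the preset 0.01, so correlated members do not account for its loss. In the other lists among the 10 these were not separated, and the cause of the loss with fry was not tested. Without replicate 1 of 11.2 mM, signs turned. Leaving out 1 array, the ATF4 stress median ranged from -1.22 to 0.045 and Dgat2 from -1.23 to 0.14. Slc7a11 ranged from -3.07 to 0.66 and Trib3 from -3.65 to 0.046, both dim on 3 arrays, so their signs are not settled. In 490 results of 49 named genes no other sign changed. Many of these could not change. The replicate block, the variance trend and the fit of named probe sets leave each log2 difference as it was. Averaging probe sets does so for a gene with 1 probe set. Of the 18 other lists, 2 passed camera in 1 alternative or more, 4 times in all, and 5 passed fry for change in either direction. The ratio of between-group to within-group differences was 1.13, 1.25 at or above the median signal and 1.13 after quantile normalization.

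The groups share the replicate numbers 1 and 2, but no label says what a number stands for, and with 2 pairs the numbers do not pair the samples. Replicate differences of the groups correlated at -0.078 over probe sets. With the replicate block, 0 probe sets were called and 2958 had an unadjusted p under 0.05, and the apoptosis list passed with adjusted p = 0.0469, against adjusted p = 0.678 with an estimated correlation and no block. Background signal was not given with the values, so dim probe sets were not told from unexpressed ones.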

Other observations

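The gene families and single genes of this paragraph were chosen after the data were seen. Of 16 families, 3 passed camera with the preset correlation. Centromere proteins were shifted higher at 22.4 mM, with a median log2 difference of 0.47 over 14 genes (adjusted p = 8.93e-06, and adjusted p = 0.613 with an estimated correlation). They passed also without replicate 1 of 11.2 mM with the preset correlation (median 0.15, adjusted p = 0.00484). Proteasome subunits were shifted higher, with 0.14 over 33 genes (adjusted p = 0.00390, and adjusted p = 0.686 with an estimated correlation), and amino acid transporters of the SLC7 and SLC38 families lower, with -0.13 over 21 genes (adjusted p = 0.0186, and adjusted p = 0.613 with an estimated correlation). Neither of these passed without replicate 1 of 11.2 mM, each with an adjusted p of 0.323, where the median was 0.046 for proteasome subunits and -0.087 for the transporters.

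Among the 62 calls of the fit restricted to probe sets with 1 gene symbol, 45 differed 2-fold or more. The groups did not overlap in 62, which the selection by p makes nearly certain. The genes of this paragraph too were picked after their values were seen. Standard errors in this paragraph are those of the fit on all probe sets. The growth factor Kitlg was higher by 2.38 (SE 0.26), with adjusted p = 0.0297 in the limma fit restricted to probe sets with 1 gene symbol. The interleukin receptor Il17rb was higher by 1.88 (SE 0.16). The insulin-responsive glucose transporter Slc2a4 was higher by 1.41 (SE 0.17) and the growth factor Hbegf by 1.19 (SE 0.12). The glycogen phosphorylase Pygl was higher by 0.93 (SE 0.10) and the signalling ligand Wnt5a by 0.87 (SE 0.10). Signals of Kitlg and Wnt5a at 11.2 mM, 5.34 and 5.38, were dim, so the sizes of their differences are not exact. On the lower side were the inositol trisphosphate kinase Itpkb with -1.73 (SE 0.15) and the sorting receptor Sort1 with -0.78 (SE 0.095). Over all 36685 probe sets the adjusted p of each was 0.237 or more.

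Of the tests that follow, that of a shift carried by 1 array and the count of splits were chosen after the result was seen, while the tests by matched random lists were set before theirs. The ATF4 stress list was lower at 22.4 mM with the preset correlation, and had adjusted p = 0.678 with an estimated correlation. A brightness-dependent offset of replicate 1 of 11.2 mM is argued against: 0% of 10000 random lists matched on brightness reached the list's median of 1.27 between the 11.2 mM replicates, and the highest reached 0.22. Without that array the median difference between glucose groups was 0.045 (adjusted p = 0.302), as it would be if this array alone carried the shift, though this does not show that glucose had no effect. Of the aminoacyl-tRNA synthetases outside the list, a class that includes ATF4 targets, 14 genes were taken. Their median difference between that array and replicate 2 was 0.44, above 100% of matched random lists. Of the 14, 9 were higher on that array and 5 lower. The random lists drew genes singly, so a family whose members move together for another reason could exceed them too. This result therefore does not single out ATF4. A candidate explanation is a stress state, such as amino acid limitation, in the cells behind that array, in a part of the ATF4 targets, and whether it came from culture or handling was not tested.

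Over all probe sets, the split by glucose gave 3344 with unadjusted p under 0.05 and the higher of the other splits gave 1559. With 3 splits of 4 arrays in all, of which 1 gave as many, no share under 0.05 can be reached.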
